A study of Mus musculus with 16 samples.

How the data were processed

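Whole uterus RNA was hybridised to 16 Agilent one-colour mouse arrays of design 014868, 4 for each of control vehicle, control dexamethasone, genistein vehicle and genistein dexamethasone. The labels state 400 ng of RNA per sample, purified on RNeasy columns with DNase treatment, and Cy3 labelling. Each array holds 45018 spots, of which 1639 are controls, and 41174 distinct probes. Per the file headers, the values are scanner intensity of each spot, background-subtracted and spatially detrended by Agilent Feature Extraction 12.0.0.7, on a linear scale and not normalized between arrays. The submitters' processing notes name version 9.5 of that program instead. The deposited series value file holds the same intensity, with a largest difference of 0 from the scanner files, so the run on it, which gave identical results, is not counted among the alternatives. Spot flags, which per the file headers are 0 or 1, were used for filtering. No column of values per sample was left unused.

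Signals were taken as log2 of the processed signal minus the 75th percentile of that array. Spots flagged as outliers were set to missing, repeated spots of a probe were averaged, and 807 probes with a missing value on an array were dropped, the lactoferrin gene Ltf among them. Its values were computed separately on 15 arrays. A probe was kept when it was well above background on at least 4 of 16 arrays, which left 32598 probes, and 4887 probes were above background on no array. The files carry no gene names, so symbols were assigned by joining RefSeq accessions without their version to the GRCm38.p6 gene annotation, which matched 28223 of 29245 RefSeq probes. The brightest kept probe stood for each gene, giving 24651 genes and unnamed targets, 16528 of them with a symbol and 8123 without. For 6062 of them more than 1 probe was kept. Zbtb16 was not measured. No genome coordinates are given, because the array grid and the gene annotation use different genome builds.

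A linear model with 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, and files were read with the data.table package, version 1.17.8. The 5 comparisons were dexamethasone against vehicle in controls, the same after genistein, the difference of these effects (interaction), and genistein against control under vehicle and under dexamethasone. P-values from limma's moderated t-test, two-sided, were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p below 0.05 was called. Where a group had no array with a signal well above background, the fold is a lower bound. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

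The 27 gene lists were written from general knowledge before the data were examined, as were the comparisons, thresholds, alternatives and the rule for named genes. They cover glucocorticoid-induced, inflammatory, interferon-stimulated, steroid receptor, estrogen-responsive, implantation, Wnt, Hox and Hedgehog, clock, immediate early, matrix, proliferation, apoptosis and insulin genes. They also cover cell markers of uterine epithelium, basal squamous epithelium, stroma, smooth muscle, endothelium, eosinophils, macrophages, neutrophils, lymphocytes, adipocytes, mesothelium, ovary and oviduct, red blood cells and mast cells. Lists were tested with limma's camera with its preset correlation of 0.01, adjusted over 135 tests (27 lists and 5 comparisons). Estimated correlations and fry were run as alternatives. Adjustment over the list alone is Benjamini-Hochberg over the measured members.

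Genes were named by a fixed rule. In each comparison these were the 8 largest rises and 8 largest falls among called genes with a symbol whose groups did not overlap. For each list these were up to 4 called members with the largest change or, where none was called, up to 2 with the smallest p. A comparison with fewer than 5 calls added its 5 smallest p-values. Always included were Nr3c1, Tsc22d3, Fkbp5, Per1, Sgk1, Zbtb16, Esr1, Pgr and Ltf. The text prints a selection of these, without genes whose other probes disagreed or whose direction turned in several alternatives unless that is stated. Other probes of a called gene in dexamethasone-treated controls were called in the opposite direction for 80 of 1511 genes with more than 1 probe, and for 138 of 1283 in the comparison of genistein with control under dexamethasone.

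The alternatives fixed beforehand were quantile normalization, median scaling, normexp background correction with offset 50, no filter and a filter on all 16 arrays, the mean of a gene's probes, every probe by itself, slide as a fixed or random block, the replicate number as a block, only the arrays compared, a variance trend, array weights, a minimum of 1.5-fold, an adjusted p below 0.1 and leaving out each array. The files lack the mean spot signal that the normexp plan named, so the median spot and local background signals were used. Alternatives added after the data were examined were leaving out 2 pairs of arrays, the brighter 3 of 5 signal classes, keeping genes with missing values, and normexp with limited local background with and without the offset.

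The method was tested on simulated data with the mean and spread of each gene on the arrays. Of 100 genes given a log2 change of 1 up or down, 42% were found in the comparison of dexamethasone in controls and 18% in the interaction, and of 100 given a change of 2, 82% and 63%. All other genes of the 24651 were left unchanged, whereas dexamethasone in controls called 5669 on the real arrays. The adjusted p depends on the share of changed genes, so 42% and 82% do not measure power for that comparison. With no simulated change, 3.63% of lists had an unadjusted camera p below 0.05. Genes were simulated independently, so this rate does not apply to lists whose members vary together on the arrays. Spots well above background made up 68.9 to 81.3% of each array. Slides were identified from the file headers: of the 5 slides, 1 held a single control vehicle array.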

Results

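Gene expression in the whole mouse uterus was measured on 16 one-colour Agilent arrays, with 4 arrays for each combination of 2 neonatal and 2 adult treatments. Pups received 50 mg/kg genistein, a soy isoflavone that binds estrogen receptors, or 20 µl of the corn oil carrier on postnatal days 1 to 5. The sample labels call this control saline and the series design text calls it corn oil. It is called the control here. Adrenals and ovaries were removed at 6 weeks of age, which takes away the main sources of corticosterone and estrogen. At 8 weeks the mice received 1 mg/kg dexamethasone, a synthetic glucocorticoid, or 100 µl saline vehicle, and the uterus was collected after 4 h. The series title gives its question as whether early genistein exposure alters glucocorticoid signalling in the adult uterus.

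The 75th percentile of spot signal lay between 948 and 2719 per array, and 68.9 to 81.3% of spots were well above background. Correlations across genes ran from 0.963 to 0.988 between arrays of one group and from 0.933 to 0.986 between arrays of different groups, and no 2 arrays were identical. The first principal component held 29.7% and the second 18.0% of the variance. On the first, control vehicle array 1 lay at -68.3, apart from the rest of its group at 18.0, 8.95 and 18.0. The genistein arrays ran there from -57.9 to -10.2. The control dexamethasone arrays lay apart from all others, from 65.0 to 102. Their 75th percentiles ran from 1987 to 2719, against 948 to 2029 on the other arrays. Dexamethasone against vehicle in controls and genistein against control under dexamethasone both rest on this group. On the second, genistein vehicle arrays 3 and 4 lay at 73.1 and 49.7, apart from the other 2 arrays of that group at -42.5 and -52.2. The labels name no animals, so p-values measure the spread between these arrays, and 4 arrays per group limit the precision. In all, 24651 genes and unnamed targets were tested, of which 16528 had a symbol. Changes below are log2 fold changes from limma with standard errors (SE), each resting on 4 arrays per group, with Benjamini-Hochberg adjusted p-values.

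Dexamethasone in mice without neonatal genistein raised classical glucocorticoid targets and lowered chemokines within 4 h. The cochaperone Fkbp5, which dampens glucocorticoid receptor signalling, rose by 4.44 (SE 0.38, 21.7-fold, adjusted p = 1.58e-05), from -3.38 ± 0.92 (SD, n = 4) to 1.06 ± 0.35 (SD, n = 4) on the scaled log2 axis. The anti-inflammatory leucine zipper gene Tsc22d3 rose by 2.42 (SE 0.22), the kinase gene Sgk1 by 2.38 (SE 0.21) and the clock gene Per1 by 1.47 (SE 0.21). Among the steepest rises were Fyb2, an adaptor of T-cell receptor signalling, at 5.73 (SE 0.28, 53.2-fold), Il13ra2, a decoy receptor for interleukin 13, at 5.54 (SE 0.49, 46.5-fold), the amino acid oxidase gene Lao1 at 4.53 (SE 0.31) and the matrix proteoglycan gene Omd at 4.28 (SE 0.31). Among the steepest falls were the monocyte chemokine Ccl7 at -4.39 (SE 0.50, adjusted p = 0.000122), the neutrophil chemokine Cxcl5 (adjusted p = 0.000522), the cytokine Il1b at -3.59 (SE 0.41) and the chemokines Ccl2 and Ccl4 at -3.47 (SE 0.39) and -3.44 (SE 0.25).

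**Figure D1:**
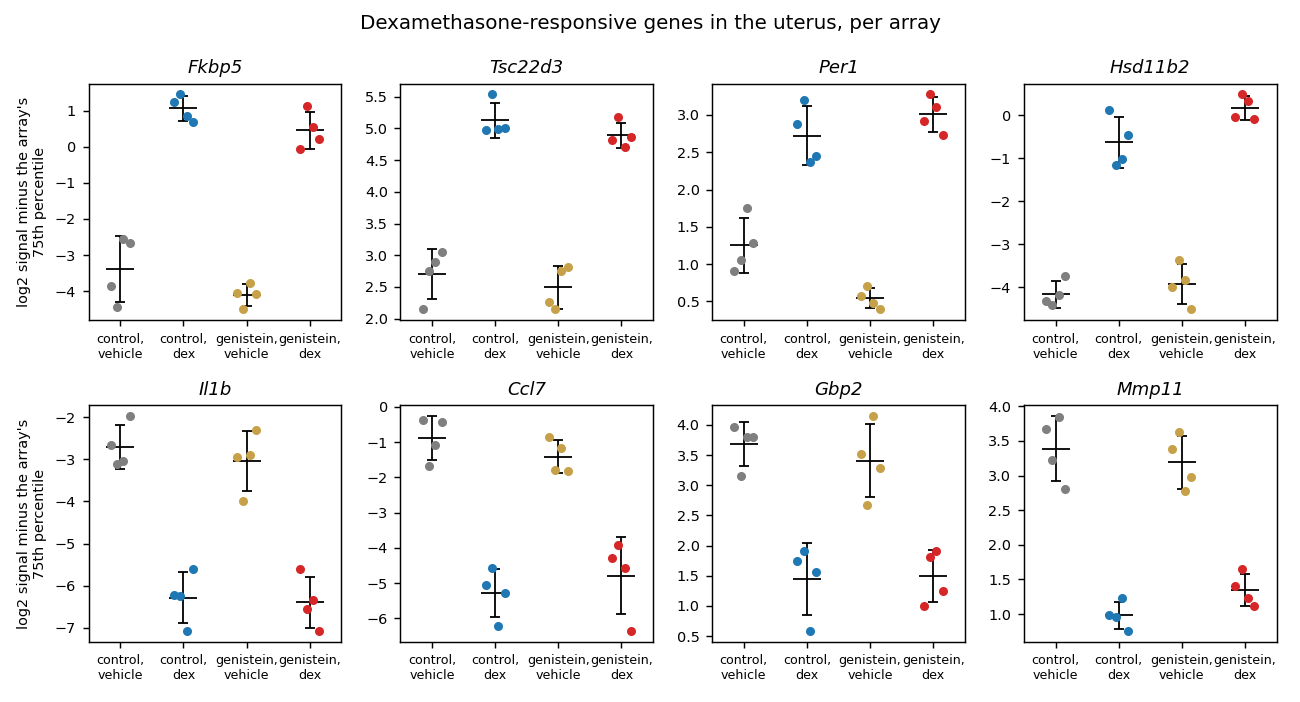
Signal of 8 genes on each of the 16 arrays, in log2 units above or below the array's own 75th percentile. Points are arrays, and bars are the group mean and SD of 4 arrays. Dexamethasone arrays lie above the vehicle arrays of the same neonatal arm for Fkbp5, Tsc22d3, Per1 and Hsd11b2, and below them for Il1b, Ccl7, Gbp2 and Mmp11.

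Of 41 measured glucocorticoid-induced genes, 26 rose, 1 fell and 14 did not pass, and 28 rose and 2 fell when adjusted over the list alone. Fam107a, a stress-responsive actin-binding gene, rose by 4.21 (SE 0.32), the haemoglobin scavenger receptor Cd163 by 3.19 (SE 0.50) and the EGF receptor inhibitor Errfi1 by 3.11 (SE 0.19). The list stood above other genes by limma's camera test (adjusted p = 6.38e-21, 0.0878 with an estimated correlation). In the list of steroid receptors and steroid metabolism, 4 of 27 rose and 5 fell, with 6 and 5 adjusted over the list alone. Hsd11b2, whose enzyme inactivates corticosterone, rose by 3.54 (SE 0.29). The glucocorticoid receptor gene Nr3c1 fell by 0.49 (SE 0.13, adjusted p = 0.0156), a call that 3 of 31 alternative settings lost. The estrogen receptor gene Esr1 changed by -0.46 (SE 0.30, adjusted p = 0.283) and the progesterone receptor gene Pgr by 0.05 (SE 0.31), and neither passed. A dimmer Esr1 probe gave -0.59 (unadjusted p = 0.00472).

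Inflammatory genes fell as a group: 18 of 33 fell, none rose and 15 did not pass, with 19 falls and 1 rise adjusted over the list alone (camera adjusted p = 5.16e-05, 0.712 with an estimated correlation). Of 30 interferon-stimulated genes, 13 fell and none rose, with 16 falls adjusted over the list alone, among them the guanylate-binding protein gene Gbp2 at -2.23 (SE 0.34). This list had a camera adjusted p of 0.000143, or 0.712 with an estimated correlation. Lymphocyte genes gave 17 falls and 1 rise among 36, and 20 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.000565, 0.712 with an estimated correlation). The T-cell receptor component Cd3d fell by 1.45 (SE 0.33). Of 30 macrophage and dendritic genes, 9 fell, including the fungal receptor Clec4n at -2.30 (SE 0.27) and the MHC class II regulator Ciita at -2.10 (SE 0.27), while 2 rose, with 11 and 3 adjusted over the list alone. Its camera call (adjusted p = 0.0487) ended in several alternatives and gave 0.776 with an estimated correlation. Neutrophil genes showed 7 falls and 2 rises among 15, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.0639). S100a9, a neutrophil calcium-binding protein gene, fell by 2.82 (SE 0.56) and the formyl peptide receptor gene Fpr1 fell by 1.95 (SE 0.25).

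Of 28 endothelial genes, 11 fell and 1 rose, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.0683). Eng and Plvap, surface proteins of vessel lining, fell, at -1.27 (SE 0.18) and -1.17 (SE 0.19), whereas Lyve1, the hyaluronan receptor of lymphatic vessels and some macrophages, rose by 2.12 (SE 0.22). Of 24 smooth muscle genes 7 fell and none rose, with 10 falls and 1 rise adjusted over the list alone, and the camera call (adjusted p = 0.0411) gave 0.807 with an estimated correlation. Pln, a calcium pump regulator, fell by 1.82 (SE 0.54) and Actg2, enteric actin, fell by 1.07 (SE 0.31), and 5 and 8 of 31 alternatives lost these calls. Among 39 matrix remodelling genes 3 rose and 8 fell, with 4 and 8 adjusted over the list alone (camera adjusted p = 0.73). The protease gene Mmp11 fell by 2.41 (SE 0.24) and the protease inhibitor gene Timp1 fell by 3.01 (SE 0.37).

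Of 35 insulin, IGF and fuel genes, 11 rose and 2 fell, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.000336, 0.395 with an estimated correlation), and the growth factor gene Igf1 rose by 2.12 (SE 0.22). Wnt, Hox and Hedgehog genes gave 4 rises and 11 falls among 42, with 5 and 12 adjusted over the list alone (camera adjusted p = 0.849). Wnt4, needed for Müllerian duct and decidual development, fell by 1.86 (SE 0.22), and the secreted Wnt modulators Dkk2 and Sfrp4 also fell, at -1.58 (SE 0.31) and -1.33 (SE 0.17). Of 32 implantation genes 4 rose and 4 fell, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.227), including the activin-binding protein gene Fst at 2.45 (SE 0.39). Of 20 clock genes 5 rose and 4 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.227). The repressor genes Nfil3 and Ciart rose by 2.80 (SE 0.15) and 1.95 (SE 0.33) and Nr1d1 fell by 1.70 (SE 0.28), another of its probes giving -0.84. Immediate early genes had 5 rises and 2 falls among 27, as they did adjusted over the list alone (camera adjusted p = 0.0204, 0.712 with an estimated correlation). Among 33 apoptosis genes 4 rose and 4 fell, with 4 and 5 adjusted over the list alone (camera adjusted p = 0.225), and the survival gene Bcl2l1, the cell cycle inhibitor gene Cdkn1a and the death gene Pmaip1 rose by 2.02 (SE 0.17), 1.63 (SE 0.27) and 1.80 (SE 0.21), other Bcl2l1 probes giving 0.92 and 0.99. The estrogen-responsive list had 4 rises and 4 falls among 36, as it did adjusted over the list alone (camera adjusted p = 0.423). Among 25 endometrial stroma genes 2 rose and 4 fell, with 2 and 7 adjusted over the list alone (camera adjusted p = 0.73), and among 16 ovary and oviduct genes 3 fell and none rose (camera adjusted p = 0.176). Mesothelial genes gave 1 rise and 2 falls of 11, mast cell genes 2 rises of 10, eosinophil genes 1 rise and 1 fall of 6, and red blood cell genes no call among 9. Uterine epithelial genes had 2 rises of 27 and basal squamous genes 2 rises and 2 falls of 22. Proliferation genes gave 2 rises of 35, among them the cyclin gene Ccne2 at 1.26 (SE 0.29).

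Adipocyte genes were higher in the control dexamethasone arrays. Of 25 measured, 13 rose and none fell, with the same numbers adjusted over the list alone (camera adjusted p = 1.42e-09, 0.712 with an estimated correlation). The leptin gene Lep rose by 4.63 (SE 1.07), the lipid droplet gene Cidec by 4.33 (SE 1.09) and the fatty acid carrier Fabp4 by 3.87 (SE 1.00), and Mrap, a melanocortin receptor accessory gene of adrenal and fat, had the largest rise of the comparison at 5.77 (SE 1.17). Array 1 of this group had an adipocyte median of -0.69 against the mean over all 16 arrays, while arrays 2, 3 and 4 had 1.59, 1.57 and 0.54. Without arrays 2 and 3 the calls of Lep, Cidec, Fabp4 and Mrap ended, and the count of changed genes was 3585. The Lep call also ended with normexp.

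Across all genes, dexamethasone changed 5669 in the controls, with 2082 higher and 3587 lower, and 9236 had an unadjusted p below the threshold. The excess of falls lay in dimmer genes. Of the dimmest of 5 signal classes 120 were higher and 751 lower (median -0.534), and of the brightest 590 and 488 (median 0.021). Differences between these groups in handling or RNA quality were not tested. The median over all genes was -0.16, against -0.0482 with quantile normalization and 0.0683 with median scaling, so changes are relative to that shift, and the median scaling called 64.8% of changed genes higher, against 36.7%. Leaving out control vehicle array 1 or control dexamethasone array 4 gave 3107 and 3565 genes, normexp background correction gave 3326, and limited normexp 11551. On slides 1, 3 and 4, and with slide as a block, the median was 1.37, 1.40, 1.30 and 1.20 for glucocorticoid-induced, -1.27, -0.492, -1.58 and -1.06 for inflammatory, -0.899, -0.545, -1.42 and -0.931 for interferon, -0.83, -0.492, -1.02 and -0.887 for lymphocyte, and 1.29, 0.402, 2.52 and 1.55 for adipocyte genes. It was -0.652, -0.273, -0.907 and -0.555 for smooth muscle, 0.209, 0.295, 0.195 and 0.215 for immediate early and 0.47, 0.303, 0.257 and 0.472 for insulin, IGF and fuel genes, while macrophage genes turned on slide 4, with -0.774, -0.546, 0.183 and -0.469.

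After neonatal genistein, dexamethasone raised and lowered many of the genes named above. Il13ra2 rose by 6.10 (SE 0.49, 68.4-fold), Fyb2 by 5.34 (SE 0.28), Fam107a by 5.00 (SE 0.32), the dipeptidase gene Dpep1 by 4.78 (SE 0.21), Lao1 by 4.76 (SE 0.31) and Fkbp5 by 4.56 (SE 0.38, 23.6-fold, adjusted p = 1.64e-05). Hsd11b2 rose by 4.11 (SE 0.29) and Tcf23, a decidual transcription factor gene, by 3.36 (SE 0.29). Per1 rose by 2.47 (SE 0.21), Tsc22d3 by 2.40 (SE 0.22) and Sgk1 by 1.51 (SE 0.21). Falls included the prion-like gene Prnd at -3.67 (SE 0.44), Ccl7 at -3.37 (SE 0.50) and Il1b at -3.36 (SE 0.41). Cxcl5 was not well above background in any genistein dexamethasone array and was at least 5.67-fold lower there (adjusted p = 0.000509). Ccl7, Il1b and Cxcl5 each lost their call under normexp.

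Of 41 glucocorticoid-induced genes 27 rose and none fell, with 30 rises and 1 fall adjusted over the list alone, and the camera call (adjusted p = 2.74e-32) held with an estimated correlation (adjusted p = 0.03). Of the 135 set tests this was the only camera call that did. Inflammatory genes gave 12 falls and no rise among 33, and 17 falls adjusted over the list alone (camera adjusted p = 9.76e-12, 0.2 with an estimated correlation). Of 30 interferon-stimulated genes 4 fell, with 12 adjusted over the list alone (camera adjusted p = 1.53e-09, 0.712 with an estimated correlation), and Gbp2 fell by 1.92 (SE 0.34). Neutrophil genes had 7 falls and no rise among 15, with 8 and 2 adjusted over the list alone (camera adjusted p = 2.48e-06, 0.248 with an estimated correlation). S100a9, Fpr2 and the resistin-like gene Retnlg fell, at -2.95 (SE 0.56), -2.75 (SE 0.42) and -2.05 (SE 0.27), although another Fpr2 probe gave -0.74. Macrophage and dendritic genes had 8 falls and 1 rise among 30, with 17 and 1 adjusted over the list alone (camera adjusted p = 1.42e-09, 0.712 with an estimated correlation), and Clec4n fell by 1.96 (SE 0.27) while Cd163 rose by 2.12 (SE 0.50), a call that 9 of 31 alternatives lost. Both called genes of the 6 eosinophil genes fell. Lymphocyte genes showed 2 rises and 2 falls among 36, as they did adjusted over the list alone (camera adjusted p = 0.204).

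Of 20 clock genes 6 rose and none fell, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.000461, 0.712 with an estimated correlation), among them Ciart at 2.15 (SE 0.33), Nfil3 at 1.79 (SE 0.15) and Per2 at 1.33 (SE 0.20), another Per2 probe giving 0.21. Implantation genes gave 6 rises and 1 fall among 32, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.00958, 0.3 with an estimated correlation), including Errfi1 at 2.89 (SE 0.19) and the patterning gene Hoxa11 at 1.46 (SE 0.25). Insulin, IGF and fuel genes had 8 rises among 35, with 11 rises and 4 falls adjusted over the list alone (camera adjusted p = 0.00833, 0.712 with an estimated correlation), and Igf1 rose by 2.10 (SE 0.22). Matrix remodelling genes had 3 rises and 7 falls among 39, with 4 and 12 adjusted over the list alone (camera adjusted p = 0.00958, 0.712 with an estimated correlation), including Timp1 at -2.04 (SE 0.37) and Mmp11 at -1.84 (SE 0.24). Wnt, Hox and Hedgehog genes gave 3 rises and 3 falls among 42, as they did adjusted over the list alone (camera adjusted p = 0.649), with Dkk2 at -2.25 (SE 0.31) and Sfrp4 2.82-fold lower. Proliferation genes had no call among 35, though the list lay lower by camera (adjusted p = 0.00398, 0.794 with an estimated correlation). Its median was -0.00682, -1.03 and 0.489 within slides 2, 3 and 4 and -0.263 with slide as a block, and its direction turned with array weights and without genistein vehicle arrays 3 and 4. That omission also ended the basal squamous call below, and the matrix and insulin calls above. Basal squamous genes had 2 falls among 22, including the cornified envelope gene Sprr1a at -1.49 (SE 0.39), a call that 20 of 31 alternatives lost, and the camera adjusted p was 0.00618, or 0.712 with an estimated correlation. Cdkn1a rose by 1.88 (SE 0.27), Zfp36, whose product destabilizes cytokine mRNA, by 1.18 (SE 0.20) and Lyve1 by 1.43 (SE 0.22), and the mesothelial gene Lrrn4 fell by 2.27 (SE 0.30). Nr3c1 fell by 0.75 (SE 0.13, adjusted p = 0.00351), with another of its probes at 0.06. Esr1 and Pgr changed by -0.78 (SE 0.30) and -0.24 (SE 0.31) and did not pass, while the dimmer Esr1 probe gave -1.01 (unadjusted p = 4.33e-05).

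None of the 25 adipocyte genes was called in this arm (camera adjusted p = 0.4), and none of the 24 smooth muscle genes (camera adjusted p = 0.811). In all, 1303 genes changed, 614 higher and 689 lower, and 4439 had an unadjusted p below the threshold. With slide as a block the count was 831, without genistein vehicle array 1 it was 862, and without genistein dexamethasone arrays 2 or 3 it was 835 and 719. Normexp gave 370, only the arrays compared 571 and array weights 6065. On slides 2, 3 and 4, and with slide as a block, the median was 1.14, 1.31, 1.35 and 1.21 for glucocorticoid-induced, -1.10, -0.777, -0.41 and -0.919 for inflammatory, -0.499, -0.868, 0.00229 and -0.567 for interferon, -1.71, -2.02, -0.82 and -1.44 for neutrophil, and -0.714, -0.748, 0.119 and -0.594 for macrophage genes. It was 0.153, 0.821, 0.212 and 0.301 for clock, 0.263, 0.442, 0.317 and 0.289 for implantation, 0.0154, 0.221, 0.104 and 0.203 for insulin, IGF and fuel, -0.448, 0.0232, -0.309 and -0.42 for matrix and -0.41, -0.495, -0.0639 and -0.305 for basal squamous genes.

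The 2 dexamethasone responses overlapped. In the same direction, 856 genes passed in both arms, 400 higher and 456 lower, against 51.9 and 100 for independent lists of these sizes, and 2 genes passed in opposite directions. The shared count was 547 without genistein dexamethasone array 3, 402 with only the arrays compared, 556 with slide as a block, 235 with normexp and 2843 with array weights. The arms share no arrays. Across genes, which are not independent replicates, the changes correlated with r = 0.401 and rho = 0.376. The 3587 genes lowered in controls had a median of -1.03 there and -0.269 after genistein, and the 689 lowered after genistein had -0.831 in controls and -0.992 after genistein. Each set was chosen in the arm where its median is the larger.

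**Figure D2:**
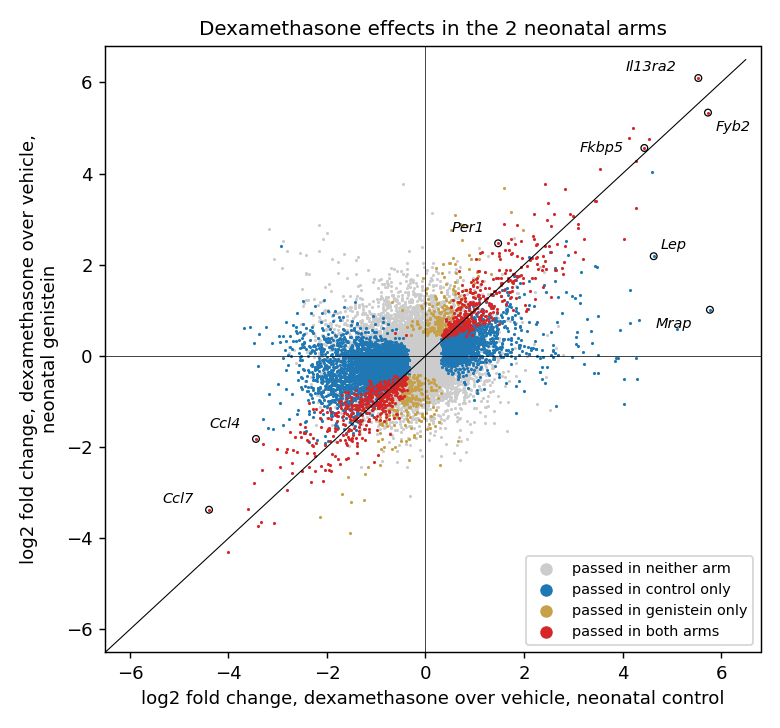
Log2 fold change of every tested gene after dexamethasone in the neonatal control arm (horizontal) and the neonatal genistein arm (vertical), with the line of equal change. Colours show where a gene passed the test, and of these 856 passed in both arms in the same direction. The difference between the arms was tested separately and called 0 genes at the reported settings.

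Whether the dexamethasone response itself differed after genistein was tested as an interaction. Fkbp5 differed between the arms by 0.12 (SE 0.54, adjusted p = 0.929) and Tsc22d3 by -0.02 (SE 0.31, adjusted p = 0.983), while Per1 differed by 1.00 (SE 0.30, adjusted p = 0.194) and Sgk1 by -0.87 (SE 0.29, adjusted p = 0.219). The smallest adjusted p was 0.162, shared by the potassium channel gene Kcnn1 at 0.91 (SE 0.14), the scaffold gene Grasp at 1.12 (SE 0.19) and the sarcomere gene Mypn at 2.44 (SE 0.42). With the same adjusted p of 0.162, Ccl4 differed by 1.62 (SE 0.35), Wnt4 by 1.27 (SE 0.31), the lipase gene Pnpla2 by -1.36 (SE 0.29), the basal cell regulator Trp63 by -1.95 (SE 0.46) and Nfil3 by -1.01 (SE 0.22), although second probes of Nfil3 and Pnpla2 gave -0.07 and -0.36. Nr3c1, Esr1 and Pgr differed by -0.26 (SE 0.18), -0.32 (SE 0.42) and -0.30 (SE 0.44), with other Nr3c1 probes at 0.56, 0.09 and 0.38. Other Fkbp5 probes gave -0.16 and 0.29.

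No gene of the 24651 passed this limma test, and 3830 had an unadjusted p below the threshold. That count was not stable: array weights called 96 genes, and normexp with extreme local backgrounds limited, added after the data were seen, called 4672 with its offset of 50 and 562 without it. Among the lists, glucocorticoid-induced genes did not differ between the arms by camera (median 0.02, adjusted p = 0.76). Adipocyte genes (median -1.46, adjusted p = 1.42e-09), basal squamous genes (-0.95, 1.09e-05), proliferation genes (-0.51, 2.61e-06), uterine epithelial genes (-0.33, 0.0199) and macrophage genes (-0.28, 0.0358) had a negative difference, after genistein minus control, by camera. Lymphocyte genes (0.61, 0.00503) and smooth muscle genes (0.45, 0.045) had a positive one. The median change in controls and after genistein was -0.52 and -0.71 for macrophage, -0.86 and -0.13 for lymphocyte and -0.70 and -0.11 for smooth muscle genes, so the first median lay further from 0 after genistein and the other 2 lay nearer to 0. With an estimated correlation these adjusted p-values were 0.712 for the adipocyte, basal squamous, proliferation and lymphocyte lists, 0.751 for the epithelial, 0.776 for the macrophage and 0.807 for the smooth muscle list. With slide as a block the medians were -1.25 for adipocyte, -0.917 for basal squamous, -0.209 for proliferation, -0.156 for epithelial, -0.165 for macrophage, 0.645 for lymphocyte and 0.293 for smooth muscle genes. The smooth muscle, macrophage and epithelial calls also ended in many other alternatives, and without genistein vehicle arrays 3 and 4 the proliferation call ended and the epithelial direction turned. Adjusted over the list alone, 3 adipocyte and 3 apoptosis genes were lower, 5 Wnt, Hox and Hedgehog and 3 implantation genes were higher, and 2 clock genes were higher and 1 lower.

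Neonatal genistein by itself, in vehicle-treated adults, left little that passed. The 1 gene called was 4930577N17Rik, of unnamed function, at 0.97 (SE 0.12, adjusted p = 0.033). It is named because it was the sole call, chosen after its values were seen, and 23 of 31 alternatives lost it. The next smallest adjusted p was 0.344, for genes such as the olfactory receptor gene Olfr53 at 0.99 (SE 0.17), Btbd8 at -0.97 (SE 0.18) and the atrial myosin gene Myl7 at 1.13 (SE 0.22). Fkbp5 changed by -0.72 (SE 0.38, adjusted p = 0.383), Tsc22d3 by -0.22 (SE 0.22), Per1 by -0.71 (SE 0.21), Sgk1 by 0.43 (SE 0.21), Nr3c1 by -0.09 (SE 0.13), Esr1 by -0.44 (SE 0.30) and Pgr by 0.39 (SE 0.31), none of which passed, and another Esr1 probe gave 0.28. The lactoferrin gene Ltf, estrogen-induced in the uterus and measured on 15 of the arrays, changed by 1.25 (SE 0.58, adjusted p = 0.362).

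Under vehicle 9 lists passed by camera with its preset correlation, and none did with an estimated correlation, where the adjusted p was 0.749 for the epithelial list and 0.712 for the other 8. Of 35 proliferation genes none passed over all genes and 6 rose adjusted over the list alone (camera adjusted p = 4.3e-12), with Ccne2 at 1.24 (SE 0.29) and the replication gene Mcm5 at 1.10 (SE 0.28). Of 22 basal squamous genes none passed over all genes and 4 rose adjusted over the list alone (camera adjusted p = 2.61e-06), with the keratin gene Krt6b at 1.74 (SE 0.47) and Sprr1a at 1.64 (SE 0.39). Uterine epithelial (0.00972), macrophage (0.00106) and adipocyte (0.000316) lists lay higher, the last with Cidec at 3.01 (SE 1.09). Glucocorticoid-induced (0.00299), smooth muscle (0.000455), clock (0.00545) and Wnt, Hox and Hedgehog genes (0.045) lay lower, the values being camera adjusted p. With slide as a block the glucocorticoid-induced call ended (adjusted p = 0.25), and without genistein vehicle arrays 3 and 4 the smooth muscle, macrophage, adipocyte and Wnt, Hox and Hedgehog calls ended and the uterine epithelial direction turned. On slides 1, 3 and 4 the smooth muscle median was -0.956, -0.437 and 0.0843, the clock median -0.404, -0.364 and -0.0113 and the Wnt, Hox and Hedgehog median -0.327, -0.661 and 0.0861. The epithelial median was 1.09, 0.814 and -0.0957, the macrophage median 0.667, 0.505 and 0.0541, the adipocyte median 0.415, 1.23 and 0.584 and the glucocorticoid-induced median -0.138, -0.0892 and -0.126. With slide as a block these 7 medians were, in this order, -0.473, -0.27, -0.211, 0.476, 0.506, 0.664 and -0.135. Retnlg, the 1 neutrophil gene higher adjusted over the list alone, stood at 1.17 (SE 0.27). Within slides 1, 3 and 4 and with slide as a block the median was 0.882, 0.746, 0.613 and 0.726 for proliferation and 0.643, 0.994, 0.528 and 0.901 for basal squamous genes. In all, limma called 1 gene higher and 0 lower, and 3427 had an unadjusted p below the threshold.

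Among dexamethasone-treated mice, those given neonatal genistein differed from controls in single genes of several kinds. The chemokine gene Ccl4 was higher by 1.68 (SE 0.25, 3.20-fold, adjusted p = 0.00283), Tnf by 1.15 (SE 0.29), Wnt4 by 1.32 (SE 0.22, adjusted p = 0.00357) and the T-cell coreceptor genes Cd4 and Cd8a by 1.18 (SE 0.22) and 1.45 (SE 0.36). The steroidogenic gene Cyp17a1 was higher by 1.31 (SE 0.29), and Cyp11a1 and the aromatase gene Cyp19a1, neither well above background in the controls, were at least 2.22-fold and 1.92-fold higher. Trp63 was lower, at -1.80 (SE 0.33, 3.48-fold), as were the hemidesmosome gene Col17a1 at -2.09 (SE 0.55), Fst at -1.52 (SE 0.39), Pnpla2 at -1.21 (SE 0.20) and Nfil3 at -1.12 (SE 0.15). The largest rises included the olfactory receptor gene Olfr1305 at 3.59 (SE 0.70, 12.1-fold), Olfr353 at least 4.26-fold and the zinc finger gene Insm2 at least 7.54-fold. Second probes of Nfil3 and Pnpla2 gave -0.16 and -0.09.

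Of 36 lymphocyte genes 14 were higher and none lower, with 19 adjusted over the list alone (camera adjusted p = 0.00261, 0.712 with an estimated correlation). Ovary and oviduct genes gave 7 higher and none lower of 16, with 8 adjusted over the list alone (camera adjusted p = 0.0389, 0.712 with an estimated correlation), a camera call lost with quantile normalization. Of 36 estrogen-responsive genes 7 were higher and none lower, with 6 adjusted over the list alone (camera adjusted p = 0.271), among them the envelope gene Sprr2e at 1.48 (SE 0.30) and the receptor partner Ramp3 at 1.01 (SE 0.24). Inflammatory genes gave 5 higher and 1 lower of 33, as they did adjusted over the list alone (camera adjusted p = 0.888). Macrophage and dendritic genes gave 4 higher and 2 lower of 30, such as the dendritic growth receptor Flt3 at 1.60 (SE 0.38), and endothelial genes 6 higher and 1 lower of 28, among them Eng at 0.68 (SE 0.18). Basal squamous genes gave 3 higher and 2 lower of 22 (camera adjusted p = 0.411), with Krt6b, not well above background in control dexamethasone arrays, at least 3.31-fold higher. Apoptosis genes gave 3 higher and 5 lower of 33 (camera adjusted p = 0.811), with Bcl2l1 at -0.91 (SE 0.17), whose other probes gave 0.11 and 0.14, and Pmaip1 at -0.77 (SE 0.21). Of 27 uterine epithelial genes none was called, and of 27 steroid receptor and metabolism genes 1 was higher and 2 were lower. Adipocyte genes gave 3 lower of 25 (camera adjusted p = 0.00297, 0.749 with an estimated correlation), a list median that was 1.34 within slide 3, -1.26 within slide 4 and -0.0566 with slide as a block.

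Glucocorticoid-induced genes were slightly lower as a list (median -0.15, camera adjusted p = 0.0292, 0.712 with an estimated correlation), with 1 higher and 3 lower of 41, a camera call lost with quantile normalization and with slide as a block. Fkbp5 differed by -0.60 (SE 0.38, adjusted p = 0.256), Tsc22d3 by -0.23 (SE 0.22), Per1 by 0.29 (SE 0.21), Sgk1 by -0.44 (SE 0.21), Nr3c1 by -0.34 (SE 0.13, adjusted p = 0.0667), Esr1 by -0.76 (SE 0.30, adjusted p = 0.0776) and Pgr by 0.10 (SE 0.31), and none passed. Other Nr3c1 probes gave 0.44, -0.32 and 0.26, and another Esr1 probe -0.15. Cyp11a1 and Cyp17a1 are enzymes of gonads and adrenals, both removed in these mice. On slides 3 and 4 and with slide as a block, the list median was 0.611, 0.661 and 0.538 for lymphocyte genes, 0.856, 0.972 and 0.899 for ovary and oviduct genes, and -0.113, -0.202 and -0.135 for glucocorticoid-induced genes.

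Olfactory, vomeronasal and trace amine receptor genes (chemosensory receptors), a group singled out after its values were seen, were higher in 238 of 557 and lower in none, with a median of 1.57. The median stayed positive, and 147 to 518 of these genes were higher, under quantile and median scaling and 3 normexp settings. In controls given dexamethasone, 114 of the 557 fell and 1 rose, and 40 to 450 fell under the same other settings, with Olfr1305 at -3.37 (SE 0.70) and the pseudogene Vmn1r-ps103 at least 3.59-fold lower. These 2 comparisons share the control dexamethasone arrays. After genistein, dexamethasone changed none of them at the reported settings (median 0.0987). With quantile normalization 1 rose, and with normexp none was called though the median was 0.905. A difference between the arms was not shown, as limma called 0 of the 557 in the interaction (median 0.968). With limited normexp it called 327 with the offset and 40 without. Of these genes 96.2% lay in the dimmest 2 of 5 signal classes. Of all genes in those classes, 751 of 4931 and 893 of 4930 fell in controls given dexamethasone, so falls were not limited to receptors. In the genistein comparison under dexamethasone 1068 and 1014 were higher. The receptor median was -5.19 on control vehicle array 1 and -6.97 to -6.25 on the other control vehicle arrays. The control dexamethasone arrays, at -7.25 to -6.85, overlapped the latter.

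**Figure D3:**
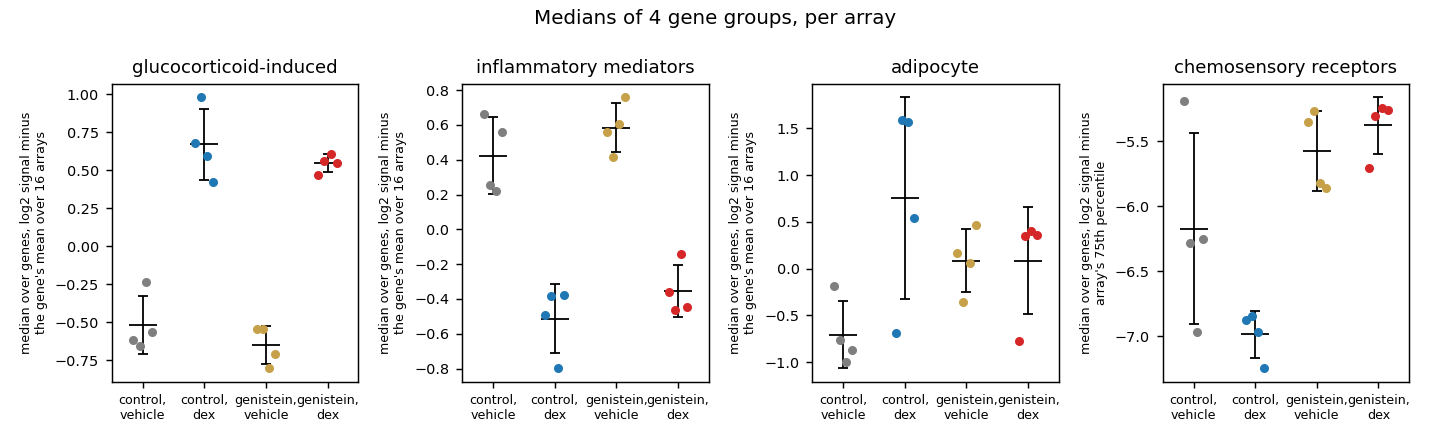
Median of 4 gene groups on each of the 16 arrays, with the mean and SD of 4 arrays per group. The vertical axis of the first 3 panels is log2 signal relative to each gene's mean over 16 arrays, and that of the last is log2 signal relative to the array's 75th percentile. The 4 control dexamethasone arrays and control vehicle array 3 lie lowest for the chemosensory receptors. The receptor median difference under vehicle was 0.632, and -0.637 with normexp. Adipocyte medians spread widely among the control dexamethasone arrays.

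Across all genes, 5654 differed, 4078 higher and 1576 lower after genistein, and 9509 had an unadjusted p below the threshold. The share higher was 72.1%, against 58.9% with quantile normalization, 56.3% with median scaling and 57.4% with slide as a block, which called 6818. Of the dimmest class of genes 1068 were higher and 160 lower, and of the brightest 638 and 330. Before scaling, the 75th percentile of signal differed by -0.572 in log2 between genistein and control dexamethasone arrays (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). The count was 2394 without control dexamethasone arrays 2 and 3, 3660 in the brighter 3 signal classes, 3297 with normexp, 9405 with limited normexp, 11033 with array weights, and 3379, 3531 and 3293 without control dexamethasone array 3, control dexamethasone array 4 or genistein dexamethasone array 3. That 5654 genes passed under dexamethasone and 1 under vehicle does not show that genistein acted differently in the 2 settings, since the test of that difference is the interaction, which called 0.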

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

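The tests of array brightness, slide, adipose tissue in 2 uteri, the shift of dim probes and an equal dexamethasone action were chosen after the result was seen. The tests on other splits of the arrays, negative control spots and adipocyte gene correlation were chosen before.

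Single arrays stood far from the other 3 of their group in 18 cases, by the gap to the nearest array divided by the range. The limit used was Dixon's critical value for 4 arrays, and chance passes it in about 1 in 20 groups. Among named genes 12 of 291 groups passed, against 14.6 by chance, among lists 5 of 108 against 5.4, and among array measures 1 of 16 against 0.8. These numbers are near what chance gives. Among lists, the ratio was 0.956 for adipocyte genes on genistein dexamethasone array 1 (-0.775, others 0.35 to 0.402) and 0.976 for lymphocyte genes on genistein dexamethasone array 4 (-0.153, others 0.265 to 0.276). It was 0.877 for red blood cell genes on control vehicle array 1, 0.901 for stroma genes on genistein dexamethasone array 3 and 0.861 for neutrophil genes on genistein vehicle array 2. The median of chemosensory receptors on genistein dexamethasone array 1 gave 0.873.

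Among genes, Ccne2 on genistein vehicle array 3 gave 0.887 and S100a9 on genistein vehicle array 2 gave 0.93. In genistein dexamethasone arrays, Cyp11a1 on array 2 gave 0.912, and Igf1 and Tnf on array 4 gave 0.835 and 0.951. In control dexamethasone arrays, Plvap and Tsc22d3 on array 2 gave 0.879 and 0.945, and Fpr2 and Krt6b on array 4 gave 0.91 and 0.854. In control vehicle arrays, Lep on array 1 gave 0.856, Fpr2 on array 2 gave 0.86 and Fst on array 4 gave 0.852.

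For 7 lists the dexamethasone effect differed between the neonatal arms by camera with the preset correlation. The adjusted p was 0.0199 for uterine epithelium, 1.09e-05 for basal squamous, 0.045 for smooth muscle, 0.0358 for macrophage, 0.00503 for lymphocyte, 1.42e-09 for adipocyte and 2.61e-06 for proliferation genes. None passed with an estimated correlation, and no single gene passed the interaction (3830 at an unadjusted p below the threshold). Of 100 drawn relabellings, 11 gave at least as many unadjusted genes, the real one included, the highest other giving 6159. The draws shuffled genistein labels within each adult treatment, so a genistein effect shared by both treatments enters some of them as an interaction. They cannot measure chance for the interaction alone, so at the reported settings chance is not excluded. With limited normexp, added after the data were seen, 2 of 100 relabellings reached the 4672 genes called (highest other 5427). Without the offset 3 of 100 reached the 562 called (highest other 2100). Both are fewer than 5 in 100, but the same limit holds, so neither measures chance for the interaction alone.

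The other counts were set against all 35 splits of the same 8 arrays. Dexamethasone in controls called 5669 genes and the highest other split 1, so 1 of 35 splits reached the real count and chance is excluded at that level. The count of 5654 for genistein under dexamethasone was likewise reached by 1 of 35 splits, the highest other calling 1. Dexamethasone after genistein called 1303, and 2 of 35 splits reached this, the other calling 1746, so the count by itself does not exclude chance at the level of 0.05. Of these genes 856 were called in the same direction in the control arm, which shares no arrays. Independent lists would give 51.9 higher and 100 lower. Those numbers treat genes as independent and ignore the spread estimate that both arms share. The overlap was also not set against relabelled arrays, so it cannot decide on chance. The split that called 1746 put genistein vehicle arrays 1 and 2 with genistein dexamethasone arrays 1 and 3. This nearly follows slide 2, and with slide as a block 831 genes were called. It also follows the second principal component. These arrays lay there from -52.2 to 20.1, and the others of the 2 groups from 43.5 to 73.1. The correlation of arrays within slides, estimated over all genes, was 0.0313. For genistein under vehicle 7 of 35 splits gave as many unadjusted genes as the 3427 seen, the highest other giving 4509, and chance cannot be excluded.

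The first pattern weighed is the genistein difference under dexamethasone, 5654 genes. Unequal array brightness as the whole cause is argued against by quantile normalization, with which 4444 of these genes were called again in the same direction. Slide as the whole cause of a difference this large is argued against by the block on slide, which called 6818. That count does not say how many of the 5654 were called again in the same direction. Slide and group were partly confounded. Control dexamethasone arrays 2 and 4 were on slide 1 and genistein dexamethasone arrays 1 and 3 on slide 2, each without the other group. Adipose tissue in control dexamethasone arrays 2 and 3 is argued against as the whole cause by the 2166 genes called again without them. An effect of neonatal genistein stays open as a hypothesis, and so do differences between the groups in handling or RNA quality, which were not tested.

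The second pattern is the chemosensory receptors, with a mean difference in receptor median of 1.61 between genistein and control dexamethasone arrays, the comparison in which the group was noticed. A background difference is argued against by the negative control spots, which differed by 0.234 (exact permutation p = 0.229). The receptors' median lay at percentile 100 of 10000 lists matched on signal, whose highest median was 0.688. The group was picked for its high values in this comparison, so that rank cannot weigh against a shift of all dim probes. Scaling by brightness is argued against as the whole cause, because without any scaling the difference was 1.04. This is smaller than the 1.61 with scaling, so a part due to scaling stays open. A difference in genomic DNA or unspliced RNA carried with the sample could also raise such genes and was not tested, and an effect of genistein remains open.

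The third pattern is the adipocyte genes in the control dexamethasone arrays. Adipose tissue carried with the uterus is consistent with their mean correlation of 0.356 among vehicle arrays alone, where lists of 25 genes matched on signal mostly gave -0.0327 to 0.0876. A dexamethasone action of one size in both arms cannot be told apart from one limited to controls. The interaction of the list passed with the preset correlation and not with an estimated one (adjusted p = 0.712). A part due to dexamethasone stays open, since uneven dissection and drug action may both contribute.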

How the results depend on the processing

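The tests with a pair of arrays left out, the brighter signal classes, missing values kept and limited normexp were chosen after the result was seen; the others were planned. Of named gene values over the alternatives, 5579 kept direction and side of the threshold, 46 gained a call, 149 lost it and 2 reversed. Of list values 3961 kept both, 150 gained, 194 lost and 15 reversed by camera's direction. Unless a cause is given, it was not tested.

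Normexp gave 3326 genes for dexamethasone in controls, 370 after genistein, 0 for genistein under vehicle, 3297 under dexamethasone and 235 shared between the dexamethasone responses. On 3 arrays, 9, 2 and 3 spots far below their local background set its fit. With those backgrounds limited the counts were 11551 for dexamethasone in controls, 9405 for genistein under dexamethasone, 0 under vehicle and 4672 for the interaction, and without the offset 562 and 0 for the last and for vehicle. At least as many interaction genes came from 2 and 3 of 100 relabellings, which do not measure chance for the interaction alone.

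Array weights gave 6065 for dexamethasone after genistein, 96 for the interaction, 2 for genistein under vehicle, 11033 under dexamethasone and 2843 shared. Slide as a block gave 831 after genistein and 556 shared, only the arrays compared 571 and 402, through fewer arrays for the variance, and an adjusted p below 0.1 gave 2046 and 1321, through its looser threshold. Without control dexamethasone arrays 2 and 3 the counts were 3585 for dexamethasone in controls and 2394 for genistein under dexamethasone, and in the brighter 3 signal classes, with fewer genes tested, 3660 for the latter. Without genistein vehicle arrays 3 and 4 the interaction called 1.

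Genistein under vehicle, 1 gene as reported, was 0 with quantile normalization, median scaling, no filter, slide as a block, only the arrays compared, a variance trend, either pair of arrays left out and the brighter classes.

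Leaving out 1 array gave 3107 to 5883 for dexamethasone in controls (3107 without control vehicle array 1, 3565 without control dexamethasone array 4). It gave 719 to 1230 after genistein (719 and 835 without genistein dexamethasone arrays 3 and 2, 862 without genistein vehicle array 1) and 0 to 1 for the interaction (1 without genistein vehicle or genistein dexamethasone array 3). For genistein under vehicle it gave 0 to 2, under dexamethasone 3293 to 5972 (3293 without genistein dexamethasone array 3, 3379 and 3531 without control dexamethasone arrays 3 and 4), and for the shared genes 547 to 807 (547 without genistein dexamethasone array 3).

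Replicate numbers did not pair the arrays: residual correlations of the 24 pairs with one number ran from -0.368 to 0.378. The replicate block gave 6080, 1356, 0, 0 and 5799 genes in the order above, and 905 shared.

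With normexp Ccne2 changed by -0.38 after dexamethasone in controls and 4930577N17Rik by -0.29 after genistein under vehicle. List values here are the list median minus that of all genes. With normexp, smooth muscle reversed to -0.036 in the interaction, and stroma to 0.31 and ovary and oviduct to -0.28 under vehicle. With array weights, uterine epithelium reversed to 0.067 in the interaction and -0.010 under vehicle, proliferation to 0.10 after genistein and interferon to 0.36 in the interaction. Without genistein vehicle arrays 3 and 4, uterine epithelium reversed to 0.052 and -0.13 in those 2 comparisons, proliferation to 0.0063 after genistein and interferon to -0.16 under vehicle, the last ranging from -0.19 (without genistein vehicle array 3) to 0.13 with 1 array left out.

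Camera's direction alone turned, with the median on the same side, for uterine epithelium after genistein (0.38 with array weights, 0.55 without the pair of genistein vehicle arrays, 0.103 as reported) and for macrophage genes in the interaction without that pair (-0.029, against -0.41).

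The series value table equals the scanner signal, gave identical results and is left out of the totals. Signal over background limits the folds given as bounds, where no array of a group was well above background.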

Other observations

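The test of a correlation between the genistein effects was chosen before its result was seen; the settings named beside it were not all planned, the brighter signal classes being added afterwards.

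The effects of genistein under vehicle and under dexamethasone rest on different arrays. Of the 5654 genes called under dexamethasone, 4648 (82.2%) had the same sign under vehicle, though at a smaller size. The genes called higher had a median of 1.06 under dexamethasone, where they were selected, and 0.279 under vehicle, and those called lower had -0.82 and -0.189. Across genes the effects correlated with r = 0.474, and 3 of 100 relabellings of the arrays gave a correlation at least as far from 0, the real one included, with others from -0.547 to 0.415. With slide as a block r was 0.608, and in the brighter 3 signal classes 0.373. A hypothesis is that neonatal genistein may have left a shift of shared direction in both settings, as the 3 of 100 argues against unrelated effects under vehicle and dexamethasone. A model of the mean effect over both settings called 5642 genes, 3809 higher and 1833 lower, with the control dexamethasone arrays contributing to both this count and the 5654. The shift may equally reflect a difference between the litters or cages of the neonatal groups, which the labels do not give.

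Genistein vehicle arrays 3 and 4 stood apart from arrays 1 and 2 on the third component too, at 64.4 and 63.4 against -18.3 and -13.7. The lone array of its slide, control vehicle array 3, was the dimmest of the 16. Per the file headers it was also scanned on another day than all the other arrays.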
